A study of Mus musculus with 64 samples.

How the data were processed

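The samples were 64 arrays of C57BL/6 mouse cerebellum, olfactory bulb, right hemisphere and spleen, with 4 conditions per tissue and 4 replicates in each of the 16 groups. The conditions were infection with Plasmodium berghei ANKA or saline injection, each with rapamycin or saline treatment. Per the labels' protocols, RNA was extracted with RNeasy columns and treated with DNase, and 5 ng of total RNA was amplified with the WT-Ovation Pico system before hybridisation to Affymetrix arrays. The deposited values are log2 signals per probe set that the authors made with RMA, per the submitters' processing notes, which give no version. Whether RMA was run over all arrays or within tissues is not given in the sources used here. The number of arrays limits the precision. The labels do not say that replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical.

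The table held 21508 probe sets with values from 2.68 to 12.8 and array medians from 6.28 to 6.51. Of these, 16426 carried 1 gene symbol, 1223 carried several and 3859 carried none, and only the first kind was tested. Entrez identifiers of 16309 of them matched the mouse reference annotation, which was used for names and changed 0 symbols. Where a symbol had several probe sets (740 genes) the one with the highest mean over all arrays was kept, which left 15481 genes. No further filter was used. The deposited table may have been filtered before, because each probe set reached at least 5.1 in 8 or more arrays while the lowest 9th-highest value was 4.18, so the genes tested may leave out genes of low signal.

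Each tissue was fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group on its 16 arrays, followed by eBayes and Benjamini-Hochberg adjustment within each comparison at a threshold of 0.05. All limma, camera and fry tests were two-sided. The 5 comparisons per tissue were infection in saline-treated mice, rapamycin in infected mice, infection in rapamycin-treated mice, rapamycin in uninfected mice, and their interaction. Differences of an effect between tissues were tested on all 64 arrays, as an F-test over the 3 brain regions and as spleen minus the mean of the brain regions. The whole-response test took the share of infection-responsive genes whose interaction opposed the infection effect, and compared it with 4900 relabellings of treatment within infected and uninfected arrays (two-sided exact permutation test), adjusted over the 4 tissues.

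Gene lists, the comparisons, the alternatives and the rule for named genes were chosen before the data were examined. Of 42 lists, 41 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, 820 list tests in all per method. Some genes, such as Cxcl10 and Vcam1, belong to more than 1 list. Named genes were the 6 largest rises and 6 largest falls past the threshold without overlap between the groups (4 and 4 outside the comparisons of infection in saline-treated and of rapamycin in infected mice), 2 members from each of the 6 lists with the lowest camera p, and 10 fixed genes. Between tissues they were the 4 with the lowest adjusted p in each direction. Without 2 groups to compare, the interaction used the threshold alone. Predicted genes and immunoglobulin or T cell receptor segments were passed over. For some named genes, values in other tissues and comparisons are given too.

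The alternatives were a fit on all 64 arrays, a fit on the 8 arrays compared, the replicate number as a block, removal of the 30% of genes with the lowest mean, eBayes with trend and robust options, arrays centred on their medians, array weights, and leaving out each array in turn. Every probe set was also tested on its own, for the counts alone, so other probe sets of named genes were not compared. Marker means as covariates were added after seeing the data. On simulated data with 200 altered genes, differences of 1 log2 were recovered for 84% to 100% and of 0.5 log2 for 24% to 92%, and between 4 and 16 other genes were called, or 44 and 41 for spleen minus brain. With a simulated response kept at 0.5 under rapamycin, the whole-response test gave exact permutation p from 0.0155 to 0.0282, and with no simulated difference it gave 0.0302 in cerebellum, 0.869 in olfactory bulb, 0.171 in right hemisphere and 0.658 in spleen, so 1 of the 4 tissues passed without a difference. The simulated genes varied independently of each other, while genes on the arrays may move together, so the simulated rates and p-values may not hold for the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.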

Results

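Gene expression was measured on 64 one-colour Affymetrix arrays of C57BL/6 mouse tissue. Mice had been injected with Plasmodium berghei ANKA, a rodent parasite strain that causes experimental cerebral malaria in this mouse strain, or with saline. Treatment was with rapamycin, an inhibitor of the mTOR kinase, or with saline. RNA came from cerebellum, olfactory bulb, right hemisphere and spleen, with 4 arrays in each of the 16 groups. The levels are log2 RMA signals, and 15481 named genes were tested. Every p-value for a gene is a Benjamini-Hochberg adjusted p from limma. In all 64 arrays the marker genes of the labelled tissue were higher than in every array of the other tissues. Replicates of a group correlated across probe sets with r between 0.963 and 0.991. Genes named for the largest changes between groups, other than for the interaction, showed no overlap between the 4 arrays of one group and the 4 of the other.

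The first question was what infection did to the brain of saline-treated mice. In all 3 brain regions the largest rises were in interferon-induced defence genes. Igtp, an immunity-related GTPase that acts on vacuoles holding intracellular pathogens, went from a log2 signal of 4.65 ± 0.32 (SD, n = 4) to 9.26 ± 0.14 in cerebellum. That is a 24.4-fold rise (adjusted p = 7.88e-16), beside 14.9-fold in olfactory bulb and 18.5-fold in right hemisphere. Iigp1, of the same family, rose 22.5-fold, 18.4-fold and 25.2-fold in cerebellum, olfactory bulb and right hemisphere. Cxcl10, a chemokine that draws CXCR3-bearing T cells, rose 8.88-fold, 11.2-fold and 9.01-fold in the same order.

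Of 16 interferon-gamma-inducible GTPases and regulators, 13 rose in cerebellum, 13 in olfactory bulb and 14 in right hemisphere, and none fell (13, 15 and 14 rose adjusted over the list alone). Type I interferon-stimulated genes rose in 17, 20 and 20 of 21 (19, 20 and 21 adjusted over the list alone), among them Bst2, which tethers budding virions, up 4.78-fold in cerebellum, 4.88-fold in olfactory bulb and 5.15-fold in right hemisphere. MHC class I presentation genes rose in 13, 15 and 14 of 16 (14, 15 and 15 adjusted over the list alone). Psmb9, an immunoproteasome subunit, rose 5.12-fold, 5.94-fold and 5.27-fold. Monocyte and macrophage markers rose in 13, 11 and 12 of 16 (14, 13 and 13 adjusted over the list alone), and Ly6c2, found on inflammatory monocytes, rose by 1.96, 1.66 and 1.70 in log2. Reactive astrocyte genes rose in 9, 11 and 11 of 18 (10, 13 and 11 adjusted over the list alone, where 1 fell in cerebellum). Gfap, the astrocyte intermediate filament protein, rose by 0.87, 1.04 and 0.96 in log2 (SE 0.14, 0.12 and 0.14). Each of these 5 lists passed in camera and held with an estimated correlation in every brain region.

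Cytotoxic effector genes rose in 4, 7 and 6 of 17 (5, 8 and 6 adjusted over the list alone), with adjusted p = 0.0105, 0.00707 and 0.0126 with an estimated correlation. Gzmb, a serine protease of cytotoxic granules, was 6.19-fold higher in cerebellum, 4.94-fold higher in olfactory bulb and 5.66-fold higher in right hemisphere. T cell markers rose in 6, 7 and 7 of 13 genes (7, 8 and 9 adjusted over the list alone), and Cd8a rose by 0.36, 0.63 and 0.40 in log2. The T cell list and the glucocorticoid-induced genes held with an estimated correlation in each region. Prf1, the pore-forming partner of granzymes, differed by 0.08, 0.03 and 0.00 in log2 (adjusted p = 0.691, 0.841 and 0.999). Its signal was low, at 5.21 to 5.42 in infected rapamycin-treated right hemisphere, under the lower quartile of every array (5.56 to 5.60). That group is not part of this comparison. Gzmb was lower still in uninfected saline-treated right hemisphere (4.63 to 4.87), and its rise was seen. A rise of Prf1 that its probe set missed is not excluded, but the low signal alone does not show that one was missed. Glucocorticoid-induced genes rose in 17, 16 and 18 of 18 (18, 17 and 18 adjusted over the list alone). Cdkn1a, which encodes the cell cycle inhibitor p21, rose 3.81-fold in cerebellum and 3.60-fold in right hemisphere. Pdk4, an inhibitor of pyruvate oxidation, rose 2.37-fold, 2.46-fold and 2.59-fold. Hmox1, which degrades heme, rose 2.73-fold, 6.95-fold and 2.85-fold.

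Among the genes named for large falls, Fabp7, a fatty acid carrier of astrocytes and their precursors, fell by 1.60, 0.84 and 1.09 in log2 (SE 0.21, 0.12 and 0.17) in cerebellum, olfactory bulb and right hemisphere. Slco1c1, a thyroid hormone transporter of the blood-brain barrier, fell by 0.97, 1.25 and 1.08. Itm2a fell by 1.23, 1.68 and 1.22, and the microRNA gene Mir384 by 1.56, 1.73 and 1.46. Car4, a membrane-bound carbonic anhydrase, fell by 1.29, 1.12 and 0.41. Blood-brain barrier endothelial markers fell in 7, 8 and 5 of 17 and rose in 5, 4 and 6 (7, 8 and 8 fell and 5, 5 and 6 rose adjusted over the list alone), with adjusted p = 0.785, 0.210 and 0.783 by camera. Astrocyte markers fell in 1, 2 and 0 of 13 and rose in 2, 0 and 1 (3, 2 and 0 fell and 2, 0 and 1 rose adjusted over the list alone), with adjusted p = 0.964, 0.759 and 0.876 by camera. In right hemisphere 8 of 18 activity-induced immediate early genes fell (9 fell and 1 rose adjusted over the list alone), with adjusted p = 0.0106 by camera and adjusted p = 0.515 with an estimated correlation.

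Infection changed 1578 genes in cerebellum (595 higher, 983 lower), 3954 in olfactory bulb (717 higher, 3237 lower) and 1662 in right hemisphere (793 higher, 869 lower). Of these, 134, 177 and 132 changed at least 2-fold. With each array centred on its median the share of higher genes was 50.2% against 37.7% in cerebellum and 42.9% against 18.1% in olfactory bulb. In the olfactory bulb, the mean of the forebrain hemisphere markers was 6.76 ± 0.23 (SD, n = 4) in infected and 7.18 ± 0.23 in uninfected saline-treated mice, and 1543 genes (408 higher, 1135 lower) were called with that mean as a covariate, a fit chosen after seeing the data. The count was 1002 in cerebellum without infected saline-treated replicate 3 and 2525 in olfactory bulb without uninfected saline-treated replicate 1. Array weights gave 3445 in cerebellum.

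**Figure D1:**
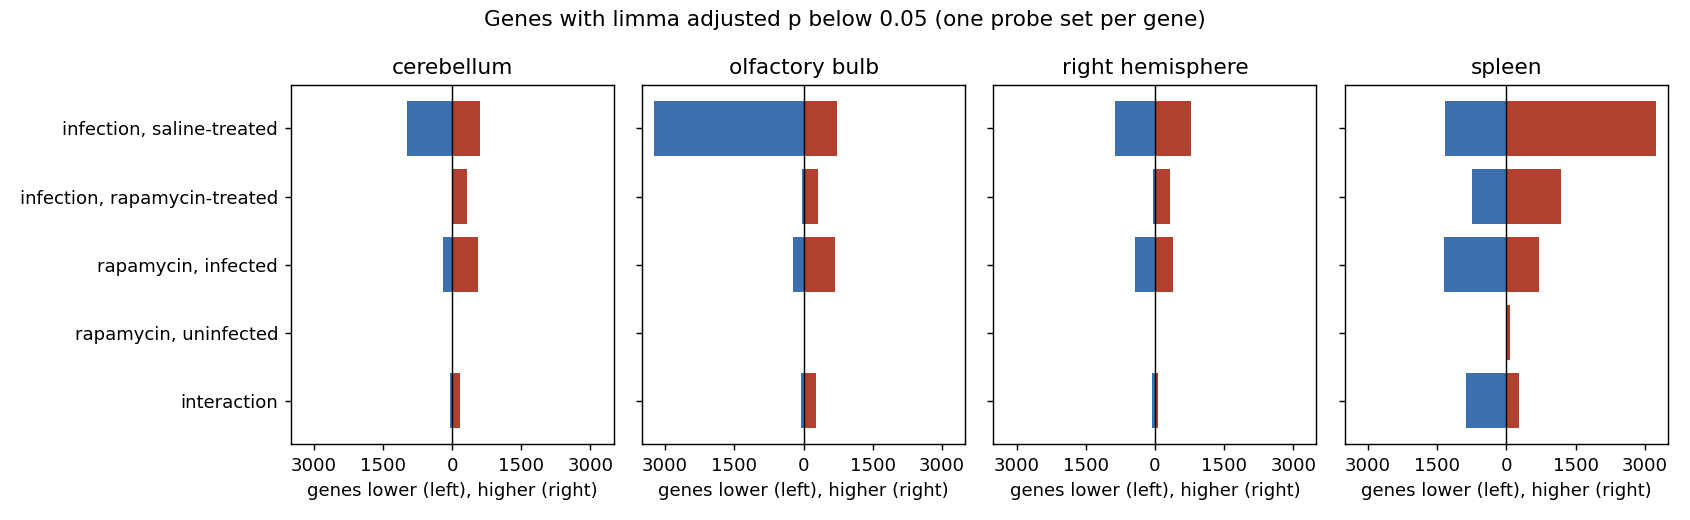
Number of genes past the adjusted p threshold for each comparison, one panel per tissue, with genes lower to the left of 0 and genes higher to the right. The longest bars are the 3252 genes higher in infected spleen and the 3237 lower in infected olfactory bulb, and the brain panels hold 0 genes for rapamycin in uninfected mice.

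In the spleen of saline-treated mice, proliferation genes and genes of T cell activation rose with infection. Gzmb rose 20.1-fold, from 5.07 ± 0.18 (SD, n = 4) to 9.40 ± 0.18 in log2 signal. Tigit and Ctla4, inhibitory receptors of activated T cells, rose 11.3-fold and 6.72-fold. Follicular helper and T cell activation genes rose in 7 of 11 (7 adjusted over the list alone), with adjusted p = 0.304 with an estimated correlation. The histone genes H2bc12 and H2ac20 rose 9.55-fold and 7.66-fold. All 34 proliferation genes rose, over all genes tested and adjusted over the list alone, with Bub1, of the spindle checkpoint, up 5.29-fold and Birc5 (survivin) up 5.02-fold. The proliferation list had adjusted p = 0.155 with an estimated correlation.

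Genes of growth and metabolism moved with them. Ribosome biogenesis genes rose in 19 of 22 (20 adjusted over the list alone), with adjusted p = 0.304 with an estimated correlation. Glycolysis genes rose in 10 of 15 (11 adjusted over the list alone), with Tpi1, triosephosphate isomerase, up 3.29-fold, and the list had adjusted p = 0.155 with an estimated correlation. Amino acid response (ATF4) genes rose in 13 of 19 (15 adjusted over the list alone), with Slc7a5, a leucine transporter subunit, up 3.03-fold, and again had adjusted p = 0.155 with an estimated correlation. Of 16 interferon-gamma-inducible GTPases and regulators, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with adjusted p = 0.340 with an estimated correlation.

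B cell and erythroid markers were among the genes that fell in the spleen. Fcer2a (CD23) and Cr2 (CD21), receptors of mature B cells, fell by 2.80 and 2.76 in log2. Of 14 B cell markers, 7 fell (7 adjusted over the list alone), with adjusted p = 0.304 with an estimated correlation. Erythroid markers fell in 7 of 12 (7 adjusted over the list alone), with adjusted p = 0.313 with an estimated correlation. Adgre4, an adhesion receptor of macrophages, fell by 3.49, and Ccr3, the eotaxin receptor, by 2.44. Splenic macrophage markers fell in 4 of 14 and rose in 4 (the same numbers adjusted over the list alone), with adjusted p = 0.273 by camera. Monocyte and macrophage markers rose in 11 of 16 and 1 fell (11 and 1 adjusted over the list alone), with adjusted p = 0.325 with an estimated correlation. Car3, which is abundant in fat and muscle, fell by 2.83 with SDs of 0.58 and 1.03 in the infected and uninfected groups.

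In all, infection changed 4586 genes in the spleen (3252 higher, 1334 lower), 519 of them at least 2-fold. With each array centred on its median 55.8% of the changed genes were higher, against 70.9%. Pancreatic acinar markers varied from array to array, with means of 8.55 ± 1.07 (SD, n = 4) in infected and 7.54 ± 2.32 in uninfected saline-treated spleens. None of the 16 lists called by camera in this comparison held with an estimated correlation. By fry 24 of 41 lists passed, not necessarily the same lists.

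The series is about rapamycin in infected mice, and in the brain interferon-stimulated genes rose further with it. Ccl12, a chemokine for monocytes, was 5.83-fold higher with rapamycin in cerebellum, 3.73-fold in olfactory bulb and 4.99-fold in right hemisphere. Oas1g, of the family that activates RNase L, rose 3.34-fold, 3.42-fold and 2.65-fold. Cxcl10 rose by another 1.08, 0.95 and 0.68 in log2 (SE 0.11, 0.24 and 0.15). Type I interferon-stimulated genes rose in 13, 9 and 12 of 21 genes in cerebellum, olfactory bulb and right hemisphere (14, 15 and 17 adjusted over the list alone). That list had adjusted p = 0.111, 0.307 and 0.0381 with an estimated correlation.

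The granzyme genes Gzmb and Gzma and glucocorticoid-induced genes fell with rapamycin. Gzmb fell by 1.31, 0.88 and 1.46 in log2 (SE 0.17, 0.18 and 0.15), to 5.99 ± 0.44 (SD, n = 4) in cerebellum, still above the 4.67 ± 0.25 of uninfected saline-treated mice. Gzma fell by 0.98 in cerebellum, 0.96 in olfactory bulb and 1.15 in right hemisphere. Of 17 cytotoxic effector genes 3, 3 and 2 fell (4 in each region adjusted over the list alone), with adjusted p = 0.111, 0.307 and 0.407 with an estimated correlation. Glucocorticoid-induced genes fell in 15, 15 and 17 of 18 (16, 18 and 18 adjusted over the list alone), and the list held with an estimated correlation in each region (adjusted p = 0.0118, 0.00547 and 0.0127). Pdk4 fell by 1.03, 1.39 and 1.26, and Cdkn1a by 1.18 in cerebellum and 1.24 in right hemisphere. Txnip, a brake on thioredoxin and glucose uptake, fell by 1.51, 1.25 and 1.43.

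Other genes that fell were Ccn1, a matricellular protein gene, by 1.72 in olfactory bulb and 1.62 in right hemisphere, and Ccl17, a ligand of CCR4, by 1.38 and 1.48. Ddit4, a stress-induced inhibitor of mTOR complex 1, fell by 0.67, 1.36 and 1.03 in cerebellum, olfactory bulb and right hemisphere. Hmox1 fell by 1.21 in olfactory bulb and by 1.01 in right hemisphere. Vcam1, an adhesion molecule of activated endothelium, rose by 0.57, 0.62 and 0.45. T cell markers fell in 2, 1 and 0 of 13 genes (5, 2 and 4 adjusted over the list alone) and had adjusted p = 0.111, 0.307 and 0.407 with an estimated correlation. Microglial markers rose in 1, 2 and 3 of 14 (3, 4 and 6 adjusted over the list alone), with adjusted p = 0.189, 0.307 and 0.257 with an estimated correlation. Cxcl9, Cd8a, Prf1 and Gfap differed by between -0.35 and 0.31 in log2 in these regions, none of them past the threshold.

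Rapamycin changed 759 genes in infected cerebellum (558 higher, 201 lower), 910 in olfactory bulb (678 higher, 232 lower) and 817 in right hemisphere (394 higher, 423 lower). After centring, 53.3% were higher in cerebellum against 73.5%, and 60.3% in olfactory bulb against 74.5%. In cerebellum the count was 447, 494 and 362 without infected rapamycin-treated replicates 1, 3 and 4, and 469, 330 and 409 without infected saline-treated replicates 2, 3 and 4; in olfactory bulb it was 600 and 458 without infected rapamycin-treated replicates 3 and 4 and 473 without infected saline-treated replicate 4; in right hemisphere it was 469 and 500 without infected rapamycin-treated replicates 1 and 4, and 1319, 503 and 464 without infected saline-treated replicates 1, 3 and 4. A fit on the 8 arrays compared gave 1507, 444 and 459 genes, array weights 2533 and 1402 in cerebellum and right hemisphere, and a fit on all 64 arrays 499 in right hemisphere.

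**Figure D2:**
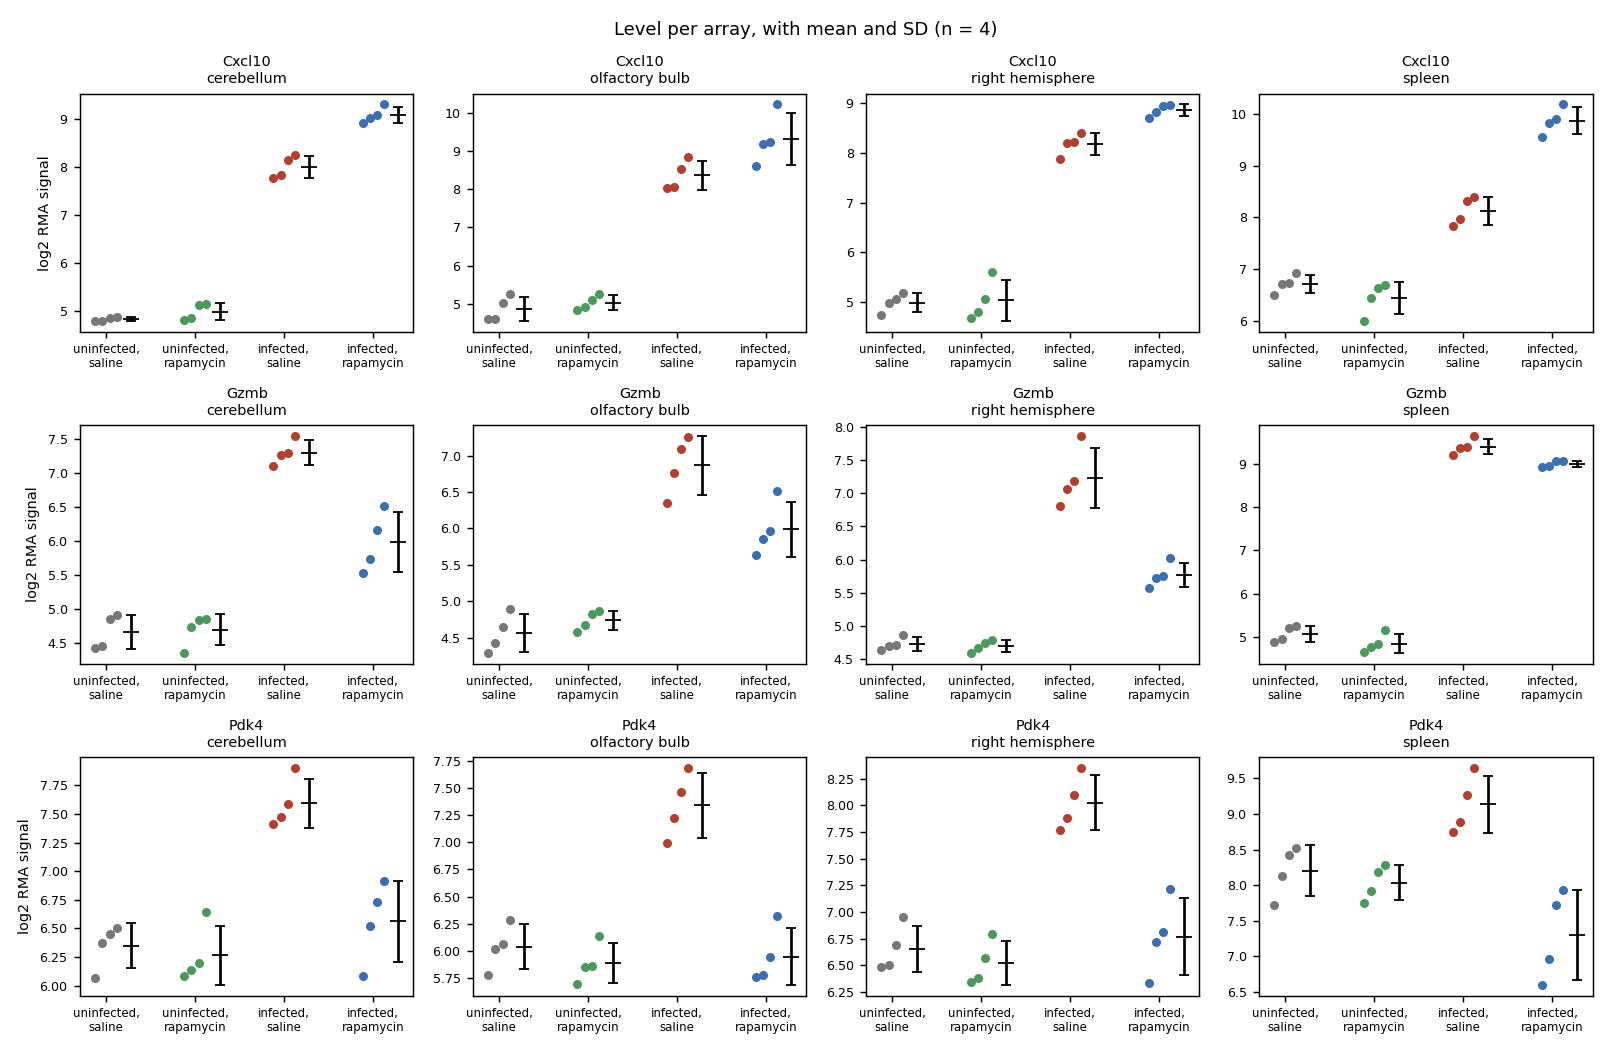
Log2 RMA signal of Cxcl10, Gzmb and Pdk4 (vertical axis) in each array, by tissue and group and with axes that start above 0 and differ between panels, with the mean and SD of the 4 arrays beside the points. In cerebellum Cxcl10 was 7.99 in infected saline-treated and 9.07 in infected rapamycin-treated mice, while Gzmb was 7.30 and 5.99.

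In the spleen of infected mice, rapamycin raised several chemokines and interferon-induced genes. Ccl2 and Ccl7, which attract monocytes, rose 6.25-fold and 5.63-fold, while the chemokine gene Ccl6 fell by 2.00 in log2. Of 16 chemokines 9 rose and 2 fell (11 and 2 adjusted over the list alone), with adjusted p = 0.0622 with an estimated correlation. Acod1, the enzyme that makes itaconate, rose 4.66-fold, and Ptgs2 (cyclooxygenase 2) 4.33-fold. Type I interferon-stimulated genes rose in 17 of 21 (19 adjusted over the list alone), with Oas2 up 3.30-fold and Usp18 up 3.15-fold, and the list had adjusted p = 0.0800 with an estimated correlation. Interferon-gamma-inducible GTPases and regulators rose in 14 of 16 (15 adjusted over the list alone), with adjusted p = 0.0622 with an estimated correlation.

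B cell genes were higher with rapamycin, while genes of division, amino acid response and plasma cells were lower. Cr2 rose by 2.03 to 9.48 ± 0.10 (SD, n = 4), against 7.45 ± 0.36 in infected and 10.21 ± 0.24 in uninfected saline-treated mice. B cell markers rose in 8 of 14 (9 adjusted over the list alone), with adjusted p = 0.0897 with an estimated correlation. Proliferation genes fell in 22 of 34 (33 adjusted over the list alone), with adjusted p = 0.158 with an estimated correlation, and Cdc20, which drives exit from mitosis, fell by 1.09. Amino acid response (ATF4) genes fell in 10 of 19 and 1 rose (14 and 1 adjusted over the list alone), with adjusted p = 0.0622 with an estimated correlation. Cholesterol biosynthesis genes fell in 9 of 18 (12 adjusted over the list alone), with adjusted p = 0.158 with an estimated correlation.

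Sdc1, the plasma cell marker CD138, fell by 1.95 and Ddit4 by 1.91. Germinal centre and plasma cell genes fell in 8 of 13 and 1 rose (10 and 3 adjusted over the list alone), with adjusted p = 0.402 with an estimated correlation. Glucocorticoid-induced genes fell in 9 of 18 (14 fell and 1 rose adjusted over the list alone), with adjusted p = 0.158 with an estimated correlation. Gzmb fell by 0.40 (SE 0.12), and Vcam1 by 0.81. Pancreatic acinar markers had a median difference of -1.33 with no member past the threshold, and means of 7.04 ± 2.04 (SD, n = 4) with rapamycin against 8.55 ± 1.07, and the list had adjusted p = 0.688 with an estimated correlation. Rapamycin changed 2060 genes here (702 higher, 1358 lower), 131 of them at least 2-fold, with 45.4% higher after centring against 34.1%. The count was 1341 without infected rapamycin-treated replicate 4, 1313 without infected saline-treated replicate 2, and 3097 in a fit on all 64 arrays.

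**Figure D3:**
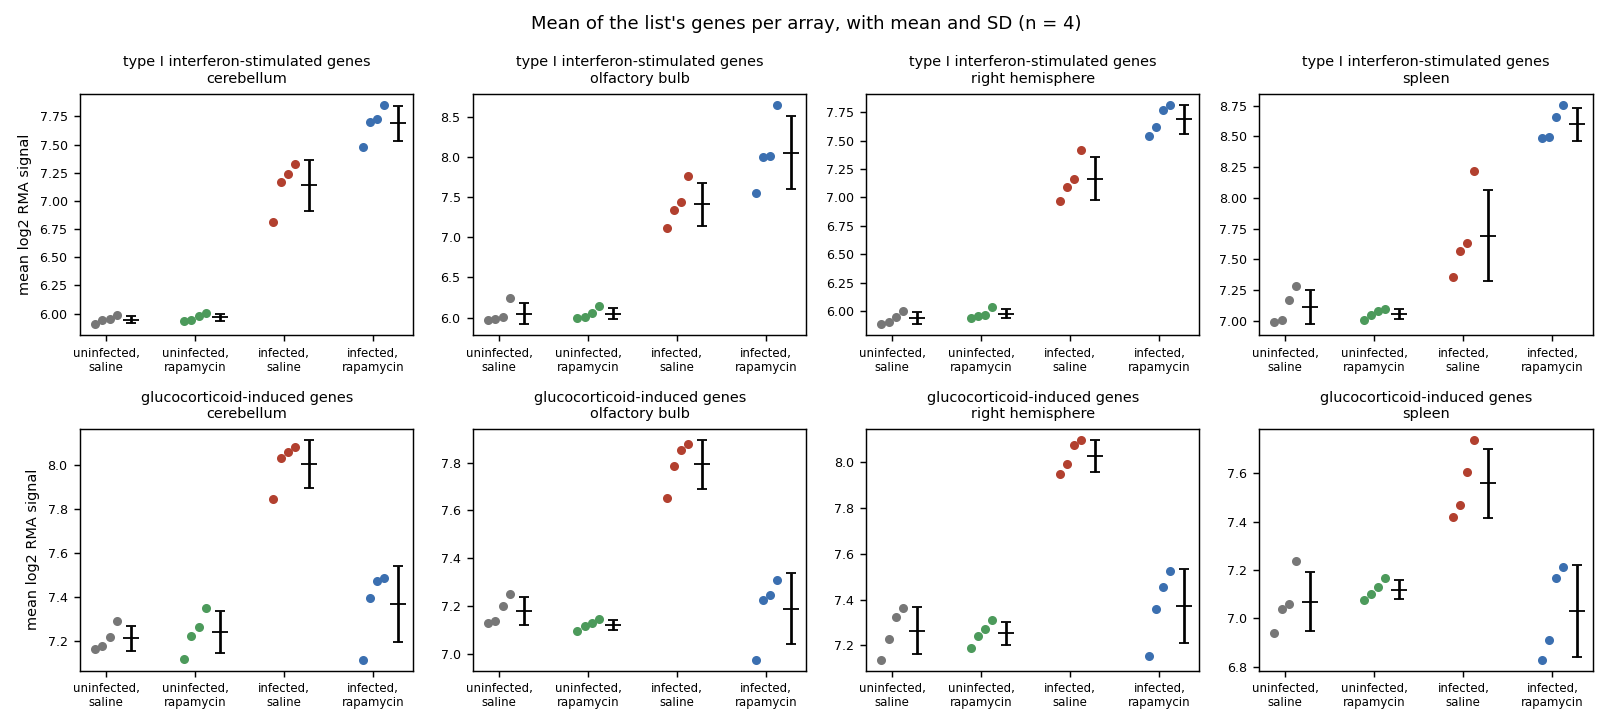
Mean log2 RMA signal of the type I interferon-stimulated genes and of the glucocorticoid-induced genes (vertical axis) in each array, by tissue and group and with axes that start above 0 and differ between panels, with the mean and SD of the 4 arrays beside the points. The median member of the glucocorticoid list differed by -0.65, -0.57, -0.64 and -0.45 with rapamycin in infected cerebellum, olfactory bulb, right hemisphere and spleen.

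Without infection, rapamycin left few changes past the threshold with the arrays grouped as labelled. In the spleen, genes of red cell precursors rose. Ermap, an erythroid membrane protein gene, rose 2.82-fold and Car2, the cytosolic carbonic anhydrase of red cells, 2.76-fold. Mgst3 rose 2.88-fold and Ctse, cathepsin E, 2.78-fold. Of 12 erythroid markers, 10 rose (12 adjusted over the list alone), and the list held with an estimated correlation (adjusted p = 0.00146). Proliferation genes rose in 5 of 34 (23 adjusted over the list alone), with adjusted p = 0.162 with an estimated correlation.

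Limma called 70 genes in uninfected spleen, 69 of them higher. The gene that was lower, Igkj1, is an immunoglobulin segment named here after its value was seen. The count was 43 and 36 without uninfected rapamycin-treated replicates 1 and 3, and 32 without uninfected saline-treated replicate 3. A fit on all 64 arrays gave 254 genes (217 higher, 37 lower), and a fit on the 8 arrays compared gave 38 (37 higher, 1 lower). Pancreatic acinar markers had a median difference of 2.08 with no member past the threshold, at 9.54 ± 0.52 (SD, n = 4) against 7.54 ± 2.32, and adjusted p = 0.405 with an estimated correlation. Limma called 0 genes in cerebellum, olfactory bulb and right hemisphere, where 657, 699 and 418 genes had an unadjusted p under 0.05. Each of these numbers is under 0.05 of the genes tested, the share that chance alone gives on average. With uninfected rapamycin-treated replicate 1 and uninfected saline-treated replicate 3 exchanged limma called 1002 genes in cerebellum, and array weights gave 8 there. An exchange of these labels is not excluded, and both arrays enter the interaction and the whole-response test in cerebellum. The rapamycin-treated array also enters infection in rapamycin-treated cerebellum (421 genes without it, 334 with it). The saline-treated array enters infection in saline-treated cerebellum (1822 without it, 1578 with it) and the tests of infection between tissues. Camera called 12 of 41 lists in uninfected olfactory bulb (10 higher, 2 lower), of which 0 held with an estimated correlation, and 0 lists in the other brain regions. In uninfected spleen it called 15 (6 higher, 9 lower), of which 1, the erythroid list, held.

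**Figure D4:**
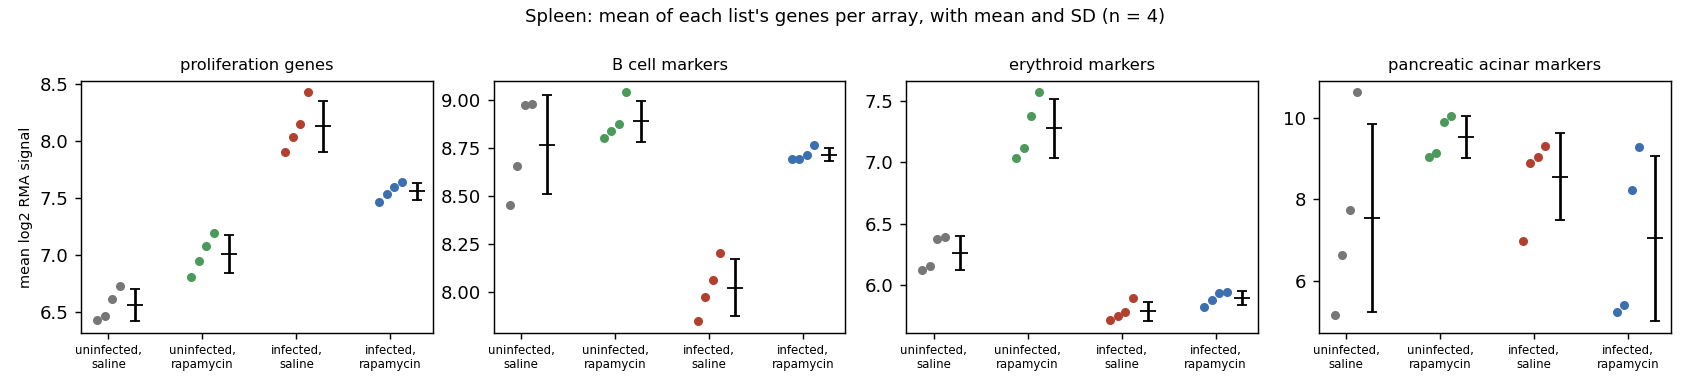
Mean log2 RMA signal of 4 gene lists in each spleen array (vertical axis), by group and with axes that start above 0 and differ between panels, with the mean and SD of the 4 arrays beside the points. Erythroid markers had a mean of 7.27 in uninfected rapamycin-treated and 6.26 in uninfected saline-treated mice, and pancreatic acinar markers lay between 5.16 and 10.63 within 1 group.

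Infection in rapamycin-treated mice again raised interferon-induced genes in the brain. Igtp rose 28.6-fold in cerebellum, 19.0-fold in olfactory bulb and 18.2-fold in right hemisphere. Ccl12 rose 22.3-fold, 27.6-fold and 27.7-fold. Type I interferon-stimulated genes rose in 20, 20 and 21 of 21 (21 in each region adjusted over the list alone), and the list held with an estimated correlation. Glucocorticoid-induced genes rose in 1, 1 and 0 of 18 (1, 2 and 2 adjusted over the list alone), with adjusted p = 0.512, 0.478 and 0.377 with an estimated correlation. Itm2a fell by 0.78, 1.06 and 0.79, and Slco1a4, an anion transporter of the blood-brain barrier, by 0.86 in olfactory bulb and 0.67 in right hemisphere.

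In the spleen of rapamycin-treated mice, infection raised Ccl2 20.9-fold and Gzmb 17.8-fold, and Tigit by 3.70 in log2. Slc4a1, the band 3 anion exchanger of red cells, fell by 2.85 and all 12 erythroid markers fell (12 adjusted over the list alone), a list that held with an estimated correlation (adjusted p = 0.00554). Pancreatic acinar markers had a median difference of -2.41, with no member past the threshold over all genes and 13 of 13 lower adjusted over the list alone, and adjusted p = 0.381 with an estimated correlation. Infection changed 334 genes in cerebellum (322 higher, 12 lower), 351 in olfactory bulb (315 higher, 36 lower), 363 in right hemisphere (332 higher, 31 lower) and 1921 in spleen (1179 higher, 742 lower). With the pancreatic marker mean as a covariate, a fit chosen after seeing the data, 1193 genes were called in spleen, and array weights gave 757 in cerebellum.

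The interaction asked whether the effect of infection differed with rapamycin. In cerebellum it was larger for Ccl12 by 2.66 in log2 (SE 0.40) and for Oas1g by 1.64 (SE 0.21), and for Cxcl10 by 0.93 (adjusted p = 0.00393). The effect on Txnip was lower by -1.54, -1.15 and -1.46 in cerebellum, olfactory bulb and right hemisphere, and that on Gzmb by -1.34, -1.05 and -1.43 (adjusted p = 0.00468, 0.0355 and 0.00278). Mir384 gave 2.14, 1.54 and 1.75, with an effect of infection nearer 0 under rapamycin. Glucocorticoid-induced genes had a lower effect in 8, 4 and 8 of 18 (15, 14 and 17 adjusted over the list alone), and the list held with an estimated correlation in these regions (adjusted p = 0.0175, 0.0161 and 0.0190).

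In the spleen the interaction was 2.76 for Ccl2 and 2.02 for Cxcl10, and -0.18 for Gzmb (adjusted p = 0.617). Proliferation genes had a lower effect in 29 of 34 (33 adjusted over the list alone), and erythroid markers in 8 of 12 (11 adjusted over the list alone). Both lists held with an estimated correlation, each with adjusted p = 0.0499. Reg2, a gene of pancreatic acinar cells, had an interaction of -5.41 (SE 1.62, adjusted p = 0.0476) with SDs from 1.71 to 2.18 within groups, and the acinar list had a median of -3.25 with no member past the threshold over all genes (13 lower adjusted over the list alone) and adjusted p = 0.339 with an estimated correlation.

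The interaction passed for 233 genes in cerebellum (177 higher, 56 lower), 334 in olfactory bulb (280 higher, 54 lower), 129 in right hemisphere (59 higher, 70 lower) and 1157 in spleen (284 higher, 873 lower). Centred, 55.9%, 60.7% and 38.6% were higher in cerebellum, olfactory bulb and spleen, against 76.0%, 83.8% and 24.5%. Leaving out single arrays gave 94 to 938 genes in cerebellum, the extremes without infected rapamycin-treated replicate 4 and uninfected rapamycin-treated replicate 1. In olfactory bulb it gave 122 without uninfected saline-treated replicate 1 and 797 without replicate 4, while the forebrain marker mean as a covariate gave 214, and in right hemisphere 54 without infected rapamycin-treated replicate 1 and 409 without infected saline-treated replicate 1. In spleen it gave 728 without infected rapamycin-treated replicate 4 and 729 without infected saline-treated replicate 2. A fit on all 64 arrays gave 708, 62 and 2166 in olfactory bulb, right hemisphere and spleen, and array weights gave 1940, 908 and 276 in cerebellum, olfactory bulb and right hemisphere. With the replicate number as a block the count in olfactory bulb was 200.

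A further test asked whether the response to infection as a whole was smaller with rapamycin, on genes chosen by their mean effect of infection over both treatments. Of 2988 such genes in olfactory bulb, 84.7% had an interaction opposite in sign to their infection effect (exact permutation p = 0.00653, adjusted p = 0.0261 over the 4 tissues). With the forebrain marker mean as a covariate, a fit chosen after seeing the data, the share was 76.3% of 2154 genes (exact permutation p = 0.0229, adjusted p = 0.0657). That mean was 6.83 ± 0.10 (SD, n = 4) in infected and 7.04 ± 0.32 in uninfected rapamycin-treated olfactory bulbs. The share in olfactory bulb came mostly from falls, with 95.0% of 2246 genes that fell and 53.6% of 742 that rose. The gap between falls and rises was 41.3 points, and 18.8 points with arrays centred. Genes that fell there had a median of -0.44 in saline-treated and -0.14 in rapamycin-treated mice, and genes that rose 0.45 and 0.38. In cerebellum the share was 67.3% of 901 genes (exact permutation p = 0.0657), in right hemisphere 71.6% of 1305 (exact permutation p = 0.0624) and in spleen 73.5% of 5037 (exact permutation p = 0.0371), each with adjusted p = 0.0657. Among genes with a mean effect of at least 1 in log2, such as Igtp, Iigp1 and Cxcl10, the share was 29.0% in cerebellum, 25.9% in olfactory bulb, 33.3% in right hemisphere and 58.1% in spleen (exact permutation p = 0.219, 0.503, 0.270 and 0.508).

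Comparing tissues asked whether the same contrast had the same effect everywhere. Cdkn1a rose by 1.93 in cerebellum and 1.85 in right hemisphere but by 0.59 in olfactory bulb, a difference among brain regions with adjusted p = 0.000152. Zfp189 was lower by -0.50 in cerebellum and -0.40 in olfactory bulb and higher by 0.47 in right hemisphere (adjusted p = 0.000152). Dlx6os2, a long noncoding RNA gene of the Dlx6 locus, was lower by -0.88 with infection in olfactory bulb and higher by 0.97 with rapamycin there, with effects between -0.01 and 0.08 in the other brain regions. Between spleen and brain, H2bc12 and Ctla4 rose more in spleen with infection (3.20 and 2.45 in log2), and the effects on Cr2 and Fcer2a were lower in spleen than in brain by -2.84 and -3.09. The mean of the B cell markers was 4.77 to 5.18 in the brain arrays, under the lower quartile of every array (5.56 to 5.60). A fall of such genes may not be seen in brain. The complement gene C4b rose by 1.69, 1.34 and 1.76 in the brain regions and differed by -0.20 in spleen. With rapamycin in infected mice, Cxcl5, a neutrophil chemokine, was 1.94 higher in spleen, and the effects on Mrap and Eaf2 were lower in spleen than in brain by -1.68 and -1.79.

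The effect of infection differed among brain regions for 123 genes and that of rapamycin for 13. These counts were 467 and 104 with array weights, and 190 and 18 with the replicate block across tissues. They were 119 and 3 without the 30% of genes with the lowest mean, and 136 and 20 after centring. Between spleen and brain, 5632 genes differed for infection (4335 higher in spleen, 1297 lower) and 2487 for rapamycin (628 higher, 1859 lower). Centring gave 54.2% higher against 77.0% for infection, and 44.0% against 25.3% for rapamycin. Counts among brain regions moved from 22 to 301 and from 2 to 30 when single replicates were left out of all tissues, lowest for infection without infected saline-treated replicate 4 or uninfected saline-treated replicate 2 and highest without infected saline-treated replicate 3, and for rapamycin lowest without infected rapamycin-treated replicate 3 or infected saline-treated replicate 4 and highest without infected saline-treated replicate 1.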

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

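Of the tests here, those on scaling of the olfactory bulb arrays and with the forebrain marker mean as a covariate, on the interaction and scaling of glucocorticoid-induced genes, on tissue splits within replicate numbers, and on pancreatic tissue and lymphocyte share in spleen were chosen after the result was seen.

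In the olfactory bulb of infected saline-treated mice 3237 of 3954 changed genes were lower. A fault of these arrays alone as the source of the falls is argued against, because 80.4% of the fallen genes and 32.4% of other genes had negative effects in both other brain regions, a gap of 47.9 points. The other genes include the 717 that rose, which may widen this gap. The test took signs only, so a fault that enlarged falls shared with the other regions is not excluded. Forebrain tissue carried in the dissected bulbs stays open: 75.3% of fallen genes and 58.2% of other genes were higher in right hemisphere than in olfactory bulb of uninfected rapamycin-treated mice, a gap of 17.1 points that is consistent with it. With the forebrain marker mean as a covariate 1135 of 1543 called genes were still lower (26.4% higher), which goes against forebrain as the whole cause but does not exclude it, because the share higher ran from 20.5% to 48.2% without single arrays (48.2% of 623 genes without uninfected saline-treated replicate 1, 39.6% of 676 without uninfected rapamycin-treated replicate 1) and was 37.7% in cerebellum. Scaling cannot be told apart from these: 42.9% of changed genes were higher after centring (41.5% to 49.3% without any 1 array) against 18.1%, but centring itself moves this balance towards even, so a share under 50% was wrongly set as evidence against scaling. The olfactory bulb markers, which carried forebrain would dilute, were at 7.40 to 7.57 in infected and 7.60 to 7.87 in uninfected saline-treated bulbs. More carried forebrain in the uninfected bulbs would give the reverse. These values, compared after the result was seen, also go against forebrain as the whole cause but do not exclude a part. An effect of infection itself stays open too.

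Glucocorticoid-induced genes were lower with rapamycin in infected mice, a list call that held with an estimated correlation in the 3 brain regions and was lost in spleen (adjusted p = 0.158 with an estimated correlation, 9 of 18 genes past the threshold). An action of rapamycin on these genes without infection is argued against, as the list mean had an interaction past the threshold in 4 of 4 tissues (exact permutation p = 0.00898, 0.0269, 0.0171 and 0.00653), and the list medians in uninfected mice were 0.01, -0.09, -0.02 and 0.01. Those p-values were not adjusted over tissues, and tissues may share animals, so they are not 4 independent tests. Scaling is argued against by the fall kept after centring, at least 90.9%, and a single array by the fall kept without it, at least 84.7%. A lower hormone response in infected mice given rapamycin may underlie the fall, as a hypothesis, and hormone levels were not analysed here.

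Erythroid markers were higher with rapamycin in spleens of uninfected mice. Pancreas carried with the spleens is argued against as the cause, because 102.9% of the rise of the list median was kept with the pancreatic marker mean as a covariate (1.04 and 1.07), while members past the threshold went from 10 to 8. A lower share of lymphocytes would raise other cell types alike, but the erythroid mean rose by 1.01 and the mean of the macrophage, neutrophil and dendritic lists differed by -0.01 (exact permutation p = 0.0286, the smallest that 4 against 4 can give). More red cell precursors, or more of their RNA, in these spleens may account for the rise and was not tested apart.

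A difference of effects between groups passed a test of that difference for 233 genes in cerebellum, 334 in olfactory bulb, 129 in right hemisphere and 1157 in spleen between treatments. Between brain regions it did for 123 genes with infection and 13 with rapamycin, and between spleen and brain for 5632 and 2487. The counts between spleen and brain may hold more false calls than the threshold implies, as they did on simulated data. Few chance splits of the arrays gave such counts, which argues against chance as their source but does not exclude it. Other splits also move real differences between treatments or tissues into the spread, which lowers their counts. The ranks, which count the real grouping as 1 of the splits, were not adjusted over the tests. Of 100 splits 1 gave as many genes in cerebellum (highest other 98) and 1 in spleen (highest other 801). In olfactory bulb 2 did (highest other 447) and in right hemisphere 3 (highest other 256), so other splits exceeded the real count there. Between tissues 1 of 100 did in each case, with highest others of 7 for infection and 5 for rapamycin among brain regions, and of 313 and 78 for spleen minus brain. Those splits moved tissue labels freely within a condition. With labels moved only among arrays of the same replicate number, which may share an animal, 1 of 100 did again, with highest others of 2, 1, 48 and 1534, and with the replicate block across tissues 190 genes differed among brain regions with infection.

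Chance is argued against likewise for the counts of the 2-group comparisons with 70 or more genes. There 1 of 35 splits, the real grouping itself, gave as many. No lower rank is possible with 35 splits and the ranks were not adjusted over comparisons, so chance is not excluded. Other splits also move the real group difference into the spread, which lowers their counts. For infection in saline-treated mice the highest other split gave 53 in cerebellum, 1598 in olfactory bulb, 42 in right hemisphere and 2 in spleen, against 1578, 3954, 1662 and 4586. For rapamycin in infected mice it gave 4, 44, 38 and 4, against 759, 910, 817 and 2060. For infection in rapamycin-treated mice it gave 0, 0, 1 and 1, against 334, 351, 363 and 1921. In uninfected spleen it gave 1 against 70. For rapamycin in uninfected brain all 35 of 35 splits gave as many as the 0 genes of limma. The highest gave 1002, 2 and 1 in cerebellum, olfactory bulb and right hemisphere. There 657, 699 and 418 genes had an unadjusted limma p under 0.05, in each region less than the share of 0.05 that chance alone gives. The 1002 in cerebellum came with uninfected rapamycin-treated replicate 1 beside uninfected saline-treated replicates 1, 2 and 4, which points to a structure of these samples. That split is the real grouping with uninfected rapamycin-treated replicate 1 and uninfected saline-treated replicate 3 exchanged, so an exchange of their labels is not excluded.

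Single arrays stood apart from the other 3 of their group in 21 of 537 sets of a named gene and group, where chance gives about 1 in 20. In cerebellum these were Bst2 at 8.58 in infected saline-treated replicate 2 (others 8.70 to 8.71), and in uninfected saline-treated mice Hmox1 at 5.67 in replicate 3 (others 6.21 to 6.28) and Oas1g at 3.96 in replicate 2 (others 3.66 to 3.68). In olfactory bulb, infected saline-treated replicate 1 stood apart for Irgm2 at 8.95 (others 8.22 to 8.29), Ccl12 at 9.22 (others 7.40 to 7.56) and Ddx58 at 6.84 (others 6.16 to 6.25). Infected rapamycin-treated replicate 1 of that tissue did for Ccn1 at 5.76 (others 6.38 to 6.46) and Itm2a at 5.69 (others 5.91 to 5.95). Also in olfactory bulb were Mir384 at 7.59 in uninfected saline-treated replicate 1 (others up to 7.08), and in uninfected rapamycin-treated mice Ccl12 at 4.67 in replicate 4 (others 5.10 to 5.15) and Pf4 at 5.74 in replicate 1 (others 5.17 to 5.25).

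In right hemisphere, infected rapamycin-treated mice had Mir384 at 6.95 in replicate 2 (others 6.25 to 6.33), Sall1 at 6.67 in replicate 4 (others 6.55 to 6.56) and Prf1 at 5.42 in replicate 1 (others 5.21 to 5.24). Ms4a4c was 4.78 in infected saline-treated replicate 4 (others 5.46 to 5.54) and Ccn1 5.66 in uninfected saline-treated replicate 1 (others 6.06 to 6.13). In spleen, Apol7c was 9.02 in uninfected saline-treated replicate 4 (others 8.46 to 8.51) and Reg2 8.30 in replicate 2 (others 3.81 to 4.06). Sdc1 was 9.56 in infected saline-treated replicate 2 (others 7.99 to 8.21), Icam1 8.22 in infected rapamycin-treated replicate 2 (others 7.87 to 7.92), and Ccl12 4.46 in uninfected rapamycin-treated replicate 1 (others 4.63 to 4.65).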

How the results depend on the processing

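The fits with marker means as covariates and the permutation of replicate numbers were chosen after the result was seen. No named gene reversed in the alternatives that compared named genes, which the test of every probe set on its own did not. The share in the whole-response test fell under 50% in each brain region among genes with at least 1 log2. For named genes, centring gave 314 values of the same sign and side of the threshold, 2 that lost and 2 that gained the call, and 4 that changed sign without a call. The fit on all 64 arrays gave 285 and 13 lost, eBayes with trend and robust 307 and 15 lost, the fit on the 8 arrays compared 253, 11 lost and 2 gained, array weights 314, 2 lost, 5 gained and 1 of changed sign, the replicate block 294, 3 lost and 1 gained, the fit without the 30% of genes with the lowest mean 256 and 1 gained, the forebrain covariate 65, 4 lost and 1 of changed sign, the pancreatic covariate 78, 1 lost and 2 of changed sign, and leaving out single arrays 2642, 165 lost, 5 gained and 20 of changed sign without a call. Deviations from the group mean of equal replicate numbers in 2 conditions of a tissue had a mean correlation of 0.021, with the own number best in 30 of 96 cases. Across tissues of 1 condition the mean was 0.068 and the own number was best in 59 of 96 (median of 10000 permutations 24, permutation p = 1e-04 one-sided, the smallest they can give), a hint from the data that equal numbers across tissues may mark shared animals, which the labels do not state. All 4 pairs were over 0.1 in 1 of 24 pairs of tissues. Of 286 list calls 105 held with an estimated correlation. The cause of the following was not tested. With array weights, infection in cerebellum gave 3445 genes in saline-treated and 757 in rapamycin-treated mice, rapamycin in infected mice 2533 in cerebellum and 1402 in right hemisphere, rapamycin in uninfected cerebellum 8, the interaction 1940, 908 and 276 in cerebellum, olfactory bulb and right hemisphere, and the brain regions differed for 467 genes with infection and 104 with rapamycin. The fit on the 8 arrays compared gave 1507, 444 and 459 genes for rapamycin in infected cerebellum, olfactory bulb and right hemisphere and 38 in uninfected spleen. The fit on all 64 arrays gave 499 and 3097 for rapamycin in infected right hemisphere and spleen, 254 in uninfected spleen, and 708, 62 and 2166 for the interaction in olfactory bulb, right hemisphere and spleen. The replicate block gave 200 for the interaction in olfactory bulb and, across tissues, 190 for brain regions with infection, 18 with rapamycin, and 5851 and 2714 for spleen minus brain. Brain regions with rapamycin gave 3 without the 30% of genes with the lowest mean, where fewer genes were tested, and 20 after centring. The forebrain covariate gave 1543 for infection and 214 for the interaction in olfactory bulb, and the pancreatic covariate 1193 for infection in rapamycin-treated spleen. With the forebrain covariate the whole-response share in olfactory bulb was 76.3% (exact permutation p = 0.0229, adjusted p = 0.0657 against 0.0261), so that forebrain carried in the bulbs stays open for this share too. The pancreatic covariate gave 73.5% in spleen (exact permutation p = 0.0449). The whole-response share among genes with at least 1 log2 was 29.0%, 25.9%, 33.3% and 58.1% in cerebellum, olfactory bulb, right hemisphere and spleen, and 73.2% after centring in cerebellum (exact permutation p = 0.0486).

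Without single arrays the counts ranged as follows. Infection in saline-treated mice gave 1002 to 1822 genes in cerebellum, 2525 to 4840 in olfactory bulb, 1174 to 2176 in right hemisphere and 3951 to 4536 in spleen. Rapamycin in infected mice gave 330 to 1006, 458 to 985, 464 to 1319 and 1313 to 1922 in the same order, and infection in rapamycin-treated mice 276 to 421, 294 to 346, 308 to 351 and 1385 to 1709. Rapamycin in uninfected mice gave 0 to 1 in cerebellum (1 without uninfected rapamycin-treated replicate 1), 0 to 0 in olfactory bulb and right hemisphere, and 32 to 80 in spleen. The interaction gave 94 to 938, 122 to 797, 54 to 409 and 728 to 1221, and the whole-response share 60.4% to 72.1%, 81.1% to 88.8%, 67.5% to 78.1% and 70.8% to 75.4%. Spleen minus brain gave 4902 to 5457 for infection and 1671 to 2394 for rapamycin.

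In the interaction of cerebellum the count was 130, 153 and 94 without infected rapamycin-treated replicates 1, 3 and 4, 938, 107, 103 and 148 without uninfected rapamycin-treated replicates 1 to 4, 137, 108 and 139 without infected saline-treated replicates 2 to 4, and 114 and 140 without uninfected saline-treated replicates 1 and 2. In olfactory bulb it was 560, 196 and 132 without infected rapamycin-treated replicates 2 to 4, 195, 204, 172 and 170 without uninfected rapamycin-treated replicates 1 to 4, 502 and 143 without infected saline-treated replicates 3 and 4, and 122, 124, 197 and 797 without uninfected saline-treated replicates 1 to 4. In right hemisphere it was 54 and 71 without infected rapamycin-treated replicates 1 and 4, 74 and 78 without uninfected rapamycin-treated replicates 1 and 4, 409, 77, 79 and 73 without infected saline-treated replicates 1 to 4, and 80, 71 and 72 without uninfected saline-treated replicates 1 to 3. In spleen it was 728 without infected rapamycin-treated replicate 4 and 729 without infected saline-treated replicate 2. Brain regions with infection gave 69, 54, 301 and 22 without infected saline-treated replicates 1 to 4 in all tissues and 36, 22 and 32 without uninfected saline-treated replicates 1 to 3, and with rapamycin 3, 4, 2 and 6 without infected rapamycin-treated replicates 1 to 4 and 30, 6 and 2 without infected saline-treated replicates 1, 2 and 4.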

Other observations

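The tests of falls against rises were chosen after the result was seen, as was the comparison of overlaps.

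Complement genes rose with infection in the brain of saline-treated mice, in 8 of 12 in cerebellum, 10 in olfactory bulb and 7 in right hemisphere (9, 11 and 9 adjusted over the list alone), and the list held with an estimated correlation (adjusted p = 0.00209, 0.00569 and 0.00193). Endothelial activation and coagulation genes rose in 4, 8 and 6 of 14 (6, 8 and 6 adjusted over the list alone, where 1 fell in cerebellum), and held too (adjusted p = 0.0224, 0.00569 and 0.00265 with an estimated correlation). Oligodendrocyte and myelin markers fell in 5 of 14 in olfactory bulb and 4 in right hemisphere (8 and 4 adjusted over the list alone), with adjusted p = 0.295 and 0.537 with an estimated correlation. The forebrain marker mean was lower too in those infected bulbs, so carried forebrain tissue stays open for the fall in olfactory bulb. In rapamycin-treated mice infection raised microglial markers in 4, 4 and 3 of 14 in cerebellum, olfactory bulb and right hemisphere (6, 5 and 6 adjusted over the list alone, where 1 fell in each of the last 2), with adjusted p = 0.00413, 0.0158 and 0.148 with an estimated correlation.

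A hypothesis was that rapamycin limits the falls of infection more than its rises in the brain. The share of genes with an opposite interaction was 96.1% of falls and 52.4% of rises in cerebellum, 95.0% and 53.6% in olfactory bulb, and 88.8% and 57.4% in right hemisphere. The difference was 43.6, 41.3 and 31.4 points, with an exact permutation p of 0.120, 0.224 and 0.236. After centring it was smaller, at 29.1, 18.8 and 27.2 points, with an exact permutation p of 0.0522, 0.289 and 0.0310. The prediction had taken a p above the threshold as evidence against the hypothesis, which was wrong, since such a p excludes nothing, and the question stays open.

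Genes that fell with infection in saline-treated mice and rose with rapamycin in infected mice numbered 383 in cerebellum, 588 in olfactory bulb, 269 in right hemisphere and 343 in spleen. Both comparisons use the infected saline-treated arrays, which links them, and independent calls would give 35.4, 142, 22.1 and 60.5. With those arrays split between the comparisons the median counts were 77.5, 222.5, 68.0 and 158. Each split fit held only part of those arrays, so its counts are lower from lost power too. The independent numbers come from the full fits and were not recomputed for the split. The drop therefore cannot be credited to the shared arrays alone. Genes that rose and then fell numbered 155, 159, 277 and 1123 (independent 7.73, 10.7, 21.7 and 285, split 50.5, 72.0, 100.5 and 533.5). Genes that rose in both comparisons numbered 55, 30, 45 and 85 (independent 21.4, 31.4, 20.2 and 147, split 28, 20, 34.5 and 54), above the independent numbers in cerebellum and right hemisphere and below them in olfactory bulb and spleen. Genes that fell in both numbered 0, 0, 0 and 13, below the independent numbers in each tissue. The correlation across genes of the effects was -0.539, -0.541, -0.537 and -0.571, against -0.499, -0.498, -0.500 and -0.497 simulated from the shared arrays alone and -0.389, -0.361, -0.353 and -0.448 when split, and genes are not independent replicates. The covariance was -0.0288, -0.0348, -0.0249 and -0.066, against -0.00715, -0.00766, -0.00549 and -0.01 simulated.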
